A study of Mus musculus with 8 samples.

How the data were processed

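The data are nanopore direct RNA sequencing libraries from the livers of C57BL/6JN mice, an inbred laboratory strain. Direct RNA sequencing reads native RNA molecules through a pore without reverse transcription and amplification of a cDNA copy. Per the labels' protocols, polyadenylated RNA was selected on oligo(dT) beads, an RNA adapter was ligated to the 5′ ends, and the libraries were run on MinION flow cells of chemistry R9.4.1. The submitters' processing notes name minimap2 2.24, the mouse genome build mm10 and DESeq2, the last with no stated role. The counting tool, the annotation release and the handling of reads that match several transcripts were not given in the sources used here. Families of near-identical genes, such as the Mup, Cyp2c, Cyp3a, Cyp2b, Sult2a, Serpina1, Serpina3, Gstp and Ugt2b genes and the class I histocompatibility genes, are therefore uncertain where reads could be split between members.

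Each deposited table holds whole-number counts of reads per transcript, with no normalization, and the counts of each library summed exactly to the number of mapped reads that the same file states. The deposited files list 53983 transcripts of 27453 genes, and 27335 of these genes carry a symbol. Other deposited columns give, per the file headers, the lengths of the reads assigned to each transcript, and these were used for read length only. Gene positions were taken from GENCODE mouse release M21 on mm10, which holds 53407 of the transcripts. Reads on transcripts outside that release made up at most 0.299% of a library. Immunoglobulin and T cell receptor constant genes, 3 mitochondrially encoded genes and Ddit3 were not among the features listed and were not analysed here.

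The 8 libraries form 2 groups of 4, each with 2 males and 2 females. The titles and the age field disagree. The titles begin with O or Y, and the age field gives 12 weeks for the O-titled and 80 weeks for the Y-titled libraries, while the series text speaks of young mice of about 2 months and old mice of about 18 months. Groups are named by title throughout, and fold changes are O-titled over Y-titled. The files give 8 distinct animal numbers, so each library is a separate animal. Counts of libraries of the same sex and group differed beyond sampling noise, with a chi-square over its degrees of freedom of 8.73 and 10.3 for O-titled males and females and of 5.25 and 3.92 for Y-titled males and females, so no library was treated as a repeat of another.

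Mapped reads ranged from 545171 to 2593200 per library. At that depth 3 reads, the number used as the floor of detection, correspond to between 1.16 and 5.50 CPM (counts-per-million) of mapped reads. Floors and counting intervals cover counting error only.

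Transcript counts were summed to genes and tested with edgeR 4.0.16 in R 4.3.3. Genes with enough reads were kept with filterByExpr at a minimum count of 10 by group, which left 6759 genes. Libraries were scaled by the trimmed mean of M values, and the robust quasi-likelihood test was used with Benjamini-Hochberg adjustment at 0.05. The comparison of O-titled with Y-titled libraries had sex as a covariate, and the comparison of females with males came from the same fit. A fit with 4 groups of sex and title gave the differences within each sex, with the spread shared over all 8 libraries, and the test of whether the O-titled versus Y-titled difference itself differed between the sexes. Unless stated otherwise, adjusted p values come from this edgeR test. Expression is given as CPM of the reads in tested genes, scaled by the same factors, as mean ± SD. Standard errors of log2 fold changes were derived from the fold and its F statistic.

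Gene lists for liver functions, sex-biased genes, cell types and core processes, 48 in all, were written before the data were examined. The 39 lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values with the preset correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry, a rotation test of each list by itself, were the alternatives. Of the list of nuclear oxidative phosphorylation genes, 75 of 90 symbols were found, since the files carry other symbols for the rest. Transcript usage within genes was tested with diffSpliceDGE of edgeR, with Simes adjusted p values per gene. Library composition was compared with exact two-sided permutation tests over the 70 assignments of 4 against 4, whose smallest possible p is 0.0286. Genes under the count filter were compared with the same exact test, with 0.5 CPM added before taking the log2, and their ratios carry exact binomial intervals at 95% confidence.

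The genes named in the text follow a rule also written beforehand. For each comparison of 2 groups it takes, among genes at an adjusted p of 0.05 or less whose values lay apart within each sex or title group, the 10 with the largest rise, the 10 with the largest fall and the 5 most abundant in each direction, leaving out predicted genes with Gm or Rik symbols. It adds the 10 genes with the smallest p for the difference between the sexes, up to 4 members with the smallest p of each list past its threshold and of the list of DNA methylation and hydroxymethylation genes, the 10 smallest p for transcript usage, and always Xist, the Y-linked genes, Tet1, Tet2, Tet3, Dnmt1, Dnmt3a and Alb. Genes outside the rule are marked as chosen after their values were seen, and a few genes that the rule takes are not reported here.

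The pipelines were tested on simulated counts with known changes. In the simulated comparison of O-titled with Y-titled libraries, on 6753 genes, edgeR found 79% of 2-fold and 91% of 4-fold changes, and 4.49% of its calls were false. For females against males, on 6793 genes, these values were 73%, 93% and 5.14%, and for the difference between the sexes, on 6813 genes, 16%, 65% and 8.99%. Camera called all 5 of the moved lists and none of the 15 unmoved ones, in data without correlation between genes. For transcript usage, with odds changed 4-fold in 200 of 1168 genes, diffSpliceDGE found 87.5% with 1.13% false calls; these simulated transcripts varied independently of each other.

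The alternatives tried were size factors by relative log expression, no filter and a stricter filter on low counts (at least 20 counts in 4 libraries), DESeq2 1.42.0, limma voom, leaving out each library in turn, no covariate, the replicate number as a block, leaving out mitochondrial and the 10 most abundant genes, leaving out the Mup, immunoglobulin and haemoglobin families, and testing transcripts in place of genes. Alternatives added after the data had been seen were thinning of all libraries to 545171 reads, a limma test of the log2 odds of each transcript within its gene, and the list settings and left-out libraries for the age-linked genes and the library composition. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.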

Results

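Polyadenylated RNA from 8 mouse livers was read molecule by molecule on nanopore flow cells. There were 4 libraries titled O and 4 titled Y, each set with 2 males (replicates 1 and 2) and 2 females (replicates 3 and 4). The series asks how liver transcription differs between young and old mice. Its title ties the question to hydroxymethylation of DNA in gene bodies, which is not analysed here. Which of the sets is the old set stayed open, because the age field gives 12 weeks for O-titled and 80 weeks for Y-titled animals while the series text contrasts about 2 with about 18 months. The O-titled libraries held 2593200, 792004, 1094237 and 1369069 mapped reads and the Y-titled ones 1722220, 545171, 1112758 and 1148108. Means in CPM are given ± SD with n = 4 libraries per group, and 6759 genes had enough reads to be tested.

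The recorded sexes matched the sex-linked genes. Xist, the RNA that coats the inactive X chromosome, had 36, 53, 34 and 32 reads in the females and 3, 0, 0 and 0 in the males, with the 3 reads in the deepest library. Ddx3y, Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome, had 0 reads in each female library.

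The O-titled livers differed from the Y-titled ones in genes of the circadian clock, of sterol synthesis, of the acute phase response and of male-specific liver expression, although no gene list kept its call with an estimated correlation. Usp2, a clock-controlled ubiquitin protease, was at 30.4 ± 12.6 CPM in O-titled and 1.16 ± 0.895 CPM in Y-titled libraries (adjusted p = 6.26e-05), where it had 6 reads in all and lay under the floor of 3 reads in 3 of 4 libraries. Lcn2, the iron-sequestering lipocalin of the acute phase, rose from 13.7 ± 5.50 to 201 ± 167 CPM, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 22.7 ± 9.34 to 115 ± 56.0 CPM. The mitochondrial protease subunit Clpx fell from 175 ± 44.7 to 34.4 ± 3.86 CPM (log2 fold -2.32, SE 0.169, adjusted p = 2.66e-07), and Selenbp2, a male-biased liver gene, fell from 276 ± 253 to 23.8 ± 16.8 CPM. On mm10, Usp2 (ENSMUSG00000032010) lies on chromosome 9 from 44067021 to 44095627 and Lcn2 (ENSMUSG00000026822) on chromosome 2 from 32384633 to 32388252. Clpx (ENSMUSG00000015357) lies on chromosome 9 from 65294260 to 65330658. Selenbp2 (ENSMUSG00000068877) lies on chromosome 3 from 94693556 to 94704413.

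In all, 271 of 6759 genes passed the edgeR quasi-likelihood test at an adjusted p of 0.05, 141 higher and 130 lower in O-titled livers, and 127 of them differed by more than 2-fold. Besides the genes above, and among genes whose values lay apart within each sex, the largest rises were in the vitamin transporter Slc5a6 (log2 fold 2.61), the cell cycle kinase Wee1 (2.56), the growth factor Nrg4 (2.27), the clock gene Per2 (2.06), the retinoic acid hydroxylase Cyp26a1 (2.03), the clock output factor Tef (2.02) and Coq10b (1.99), a coenzyme Q binding protein. Per2 lay under the floor of 3 reads in Y-titled replicates 2, 3 and 4, and Wee1 in Y-titled replicates 2 and 3. The sizes of these 2 rises therefore rest on few Y-titled reads. The most abundant genes that rose were Hamp, which encodes the iron hormone hepcidin (3015 ± 525 against 1367 ± 223 CPM), Itih4 (log2 fold 0.83), Rnase4 (0.93), Mat1a (0.49), the S-adenosylmethionine synthetase of hepatocytes, and Wfdc21 (0.45). With the same limit, the largest falls besides Selenbp2 and Clpx were in the adhesion gene Cdh1 (-2.88), the fatty acid elongase Elovl3 (-2.44), the steroid dehydrogenase Hsd3b5 (-2.38) and the acyl-CoA thioesterase Acot1 (-2.28). They were followed by Insig2 (218 ± 64.5 to 56.3 ± 20.7 CPM), which holds back the sterol-sensing machinery, the tight junction gene Cldn1 (-1.96), the manganese exporter Slc30a10 (-1.95) and the stress hormone Gdf15 (-1.88). The most abundant genes that fell were the fatty acid carrier Fabp1 (10388 ± 1780 in Y-titled against 6208 ± 1451 CPM in O-titled libraries), the plasma protein Ahsg (-0.57), the protease inhibitor Serpina3k (-1.67), the respiratory chain gene mt-Nd4l (-0.61) and the carbonic anhydrase Car3 (-0.64). The differences of Lcn2, Fabp1 and Serpina3k were larger in females (log2 folds 4.44, -1.23 and -2.27) than in males (2.16, -0.28 and -1.08), at adjusted p of the difference 0.0179, 0.0344 and 0.0262. In males Fabp1 did not pass (adjusted p = 0.557). Albumin (Alb), the most abundant plasma protein, did not pass, at 57040 ± 8382 against 62310 ± 15463 CPM (adjusted p = 0.827).

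The count fell to 154 without Y-titled replicate 4 and to 176 without Y-titled replicate 3. It was 144 with all libraries thinned to the same depth, where fewer genes could be tested. Without a single library Lcn2 (adjusted p = 0.0953 without Y-titled replicate 4), Acot1 (0.0826 without O-titled replicate 4), Gdf15 (0.106 without O-titled replicate 1) and Ahsg (0.0550 without Y-titled replicate 3) lost their calls. Cyp7a1, Wfdc21, Mat1a, Insig2, Fabp1, Serpina3k, mt-Nd4l and Car3 did so without each of several libraries, at up to 0.145, 0.168, 0.128, 0.0901, 0.0944, 0.0879, 0.0625 and 0.0972. Slc5a6 and Per2 kept their calls wherever they were tested, but the size of their rise moved. The log2 fold ran from 2.39 to 3.93 for Slc5a6 and from 1.89 to 2.79 for Per2.

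Of the circadian clock list, 14 members were tested, of which 6 rose, 1 fell and 7 did not pass (9 and 3 adjusted over the list alone), with a median log2 fold of 0.93. Usp2, Tef, Per2 and Bhlhe40, a light- and feeding-responsive repressor of the clock (44.4 ± 5.21 to 105 ± 22.5 CPM, adjusted p = 1.67e-04), led the rises. Per1 and Nr1d2 also rose and Nfil3, which opposes Tef at shared target sites, fell by 1.12 on the log2 scale (adjusted p = 0.0189); these were named after their values were seen. The camera test of the list gave an adjusted p of 3.09e-04, with adjusted p = 0.282 with an estimated correlation.

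**Figure D1:**
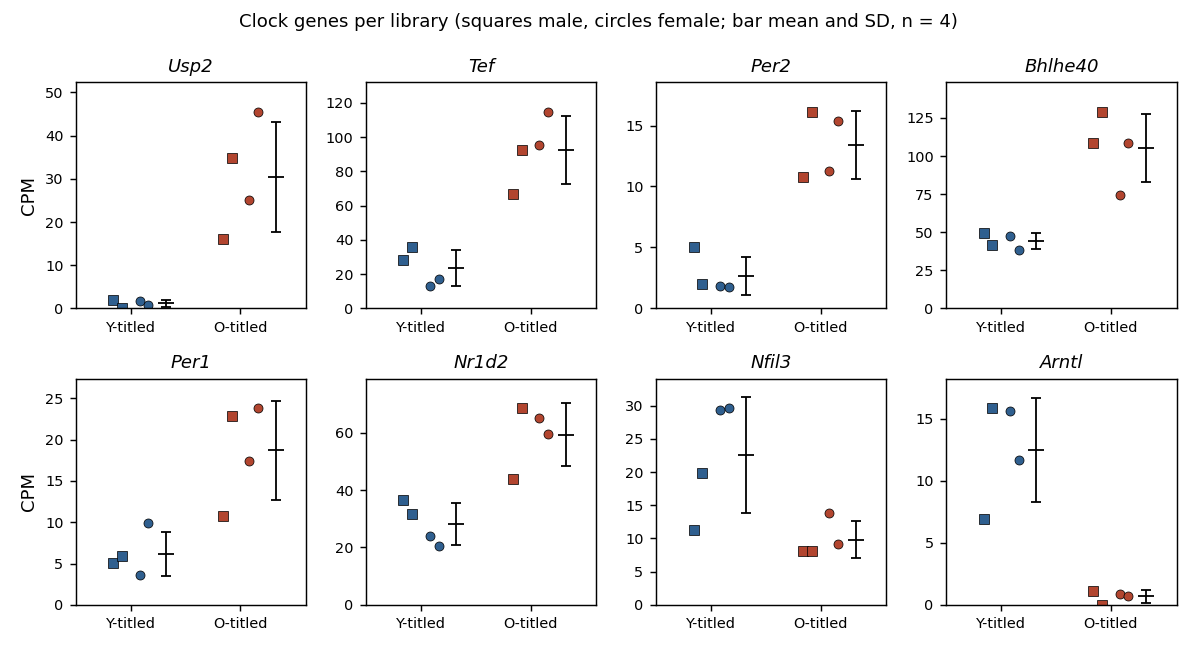
Expression of 8 clock genes per library, in CPM, with Y-titled libraries on the left and O-titled ones on the right of each panel; squares are males, circles females, and the bar is the mean and SD of 4 libraries. The O-titled values lie above all Y-titled values for Usp2, Tef, Per2, Bhlhe40, Per1 and Nr1d2, and below all of them for Arntl, which had too few reads for the edgeR test; for Nfil3 only O-titled replicate 3 exceeds a Y-titled library.

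Several genes of the cholesterol synthesis list were higher in O-titled livers. Of 25 tested members 11 rose, 0 fell and 14 did not pass, and 17 rose adjusted over the list alone. They included the sterol oxidase Msmo1 (210 ± 35.6 to 346 ± 39.9 CPM, log2 fold 0.71) and the squalene synthase Fdft1 (log2 fold 0.70). The median was 0.54 and the camera adjusted p was 8.20e-15, with adjusted p = 0.282 with an estimated correlation. Srebf1, the transcription factor that drives fatty acid synthesis, rose from 88.9 ± 24.4 to 297 ± 68.3 CPM (log2 fold 1.76, SE 0.122, adjusted p = 2.39e-07). It was the only 1 of 18 fatty acid synthesis genes that passed, also adjusted over the list alone, and that list had a median of 0.30 (camera adjusted p = 5.38e-04, but adjusted p = 0.431 with an estimated correlation).

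Several acute phase genes, which encode plasma proteins made by the liver in inflammation, were higher in O-titled livers. Of 24 tested members 5 rose, namely Lcn2, Hamp, Itih4, Apcs and Steap4, 0 fell and 19 did not pass, and 10 rose adjusted over the list alone. Serum amyloid P component Apcs rose from 277 ± 62.7 to 483 ± 112 CPM and the metalloreductase Steap4 from 88.1 ± 12.4 to 152 ± 31.2 CPM. The median log2 fold was 0.80 and the camera adjusted p was 1.29e-11, with adjusted p = 0.282 with an estimated correlation.

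Several genes that are higher in male than in female liver were lower in O-titled livers. Of 19 tested members 6 fell, Selenbp2, Elovl3, Hsd3b5, Keg1, Ugt2b1 and Cyp4a12a, 0 rose and 13 did not pass, with 9 falling adjusted over the list alone. The fall of Cyp4a12a rests on the males, since among the females only Y-titled replicate 4 had any reads of it (0.898 CPM). Keg1, a glycine acyltransferase-like gene, fell from 160 ± 47.8 to 58.9 ± 28.7 CPM and the glucuronosyltransferase Ugt2b1 from 375 ± 216 to 176 ± 82.3 CPM. The median was -1.19 and the camera adjusted p 5.07e-15, with adjusted p = 0.129 with an estimated correlation. The Mup genes, male-biased urinary proteins, took 0.287% of the reads in O-titled replicate 3 and between 3.04% and 4.65% in the other females. Of 20 tested female-biased genes 4 rose, among them the sulfotransferases Sult2a1 (log2 fold 2.27) and Sult2a2 (1.51), 0 fell and 16 did not pass, and 5 rose and 1 fell adjusted over the list alone. The rises of Sult2a1 and Sult2a2 rest on the females, since males had almost no reads of either gene. The female-biased list reached a camera adjusted p of 0.0304, with adjusted p = 0.678 with an estimated correlation. Of 10 tested genes of the growth hormone and insulin-like growth factor axis, Igf1, the growth factor made under growth hormone control, fell from 637 ± 94.8 to 455 ± 32.9 CPM (not called without each of 3 libraries, adjusted p up to 0.0861) and 9 did not pass. Adjusted over the list alone 1 rose and 5 fell (camera adjusted p = 0.00591, adjusted p = 0.368 with an estimated correlation).

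Several genes of the unfolded protein response, which act in protein folding in the endoplasmic reticulum, were lower in O-titled livers. In the unfolded protein response list 4 of 18 tested members fell, 0 rose and 14 did not pass, and 8 fell adjusted over the list alone. The chaperone Hspa5 (BiP) fell from 587 ± 166 to 348 ± 40.2 CPM, and Sdf2l1, Creld2 and Manf, which assist folding in the same compartment, had log2 folds of -1.21, -1.07 and -0.98. Manf was not called without each of 5 libraries (adjusted p up to 0.136). The median was -0.38 and the camera adjusted p 1.68e-08, with adjusted p = 0.368 with an estimated correlation.

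Few mitochondrial and fatty acid oxidation genes passed. None of the 75 tested nuclear oxidative phosphorylation genes passed in edgeR, DESeq2 or limma voom, adjusted over the list alone the edgeR count was also 0, and 21 had an unadjusted p under 0.05 in edgeR. Their median log2 fold was -0.16 (camera adjusted p = 1.57e-09, adjusted p = 0.366 with an estimated correlation). Of 10 mitochondrially encoded genes only mt-Nd4l fell, with 3 falling adjusted over the list alone (median -0.36, camera adjusted p = 9.66e-05, adjusted p = 0.368 with an estimated correlation). In fatty acid oxidation and ketogenesis 3 of 26 fell, Acot1, Ehhadh and Etfdh, 0 rose and 23 did not pass, with 4 falling adjusted over the list alone (camera adjusted p = 3.49e-05, adjusted p = 0.368 with an estimated correlation). Ehhadh lost its call without each of 2 libraries and Etfdh without each of 7, at adjusted p up to 0.0706 and 0.146. Mitochondrially encoded reads took 7.34 ± 0.391% of O-titled and 8.76 ± 1.67% of Y-titled libraries (exact permutation p = 0.114). Y-titled replicate 4 stood apart at 11.1%, against 7.59 to 8.66% in the other Y-titled libraries, and mt-Nd4l lost its call without it as without each of 2 other libraries.

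In bile acid synthesis and transport, Cyp7a1 rose, while Hsd3b7, an enzyme of the same pathway (461 ± 39.1 to 261 ± 91.9 CPM), the phospholipid exporter Abcb4 (log2 fold -0.60, not called without each of 4 libraries, adjusted p up to 0.122) and 1 further member fell, and 12 of 16 did not pass. Adjusted over the list alone 1 rose and 6 fell, and the camera adjusted p was 0.00144, with adjusted p = 0.282 with an estimated correlation.

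Of the antigen presentation genes few passed, and none of these kept its call without each library. Of 16 class I and processing genes 2 rose, the immunoproteasome subunit Psmb10 (51.1 ± 7.96 to 79.8 ± 25.7 CPM) and H2-Q6 (19.3 ± 8.28 to 34.6 ± 8.39 CPM), and 5 rose adjusted over the list alone (camera adjusted p = 1.05e-04, adjusted p = 0.368 with an estimated correlation). Without single libraries Psmb10, H2-Q6 and the class II gene H2-Eb1 lost their calls in 5, 7 and 6 of 8 fits, at adjusted p up to 0.152, 0.124 and 0.134. Of the 4 tested class II genes H2-Eb1 rose from 18.7 ± 8.52 to 38.7 ± 17.3 CPM, 3 rose adjusted over the list alone, and the median was 1.01 (camera adjusted p = 0.00144, adjusted p = 0.368 with an estimated correlation). Markers of Kupffer cells and macrophages, which carry class II molecules, had a median of 0.45, but edgeR called 0 of 17 members, over all genes and adjusted over the list alone. In edgeR 6 had an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0 (camera adjusted p = 7.66e-05, adjusted p = 0.368 with an estimated correlation). The lysozyme gene Lyz2 stood at 244 ± 124 against 91.1 ± 7.68 CPM (adjusted p = 0.211) and Cd74 at 149 ± 69.1 against 74.6 ± 27.1 CPM (adjusted p = 0.234).

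Camera also called the lists of the proteasome, the cell cycle, and the urea cycle and amino acid breakdown, each at an adjusted p of 0.0294 and with adjusted p = 0.475, 0.368 and 0.738 with an estimated correlation. Only 2 genes in them passed, both of amino acid breakdown and both rising, also adjusted over the list alone; Prodh, the proline dehydrogenase, rose from 85.8 ± 17.5 to 149 ± 35.5 CPM but was not called without each of 4 libraries (adjusted p up to 0.0895). For the 31 proteasome and 5 cell cycle genes the edgeR count was 0, with 2 and 1 at an unadjusted p under 0.05 and 0 in DESeq2 and limma voom.

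**Figure D2:**
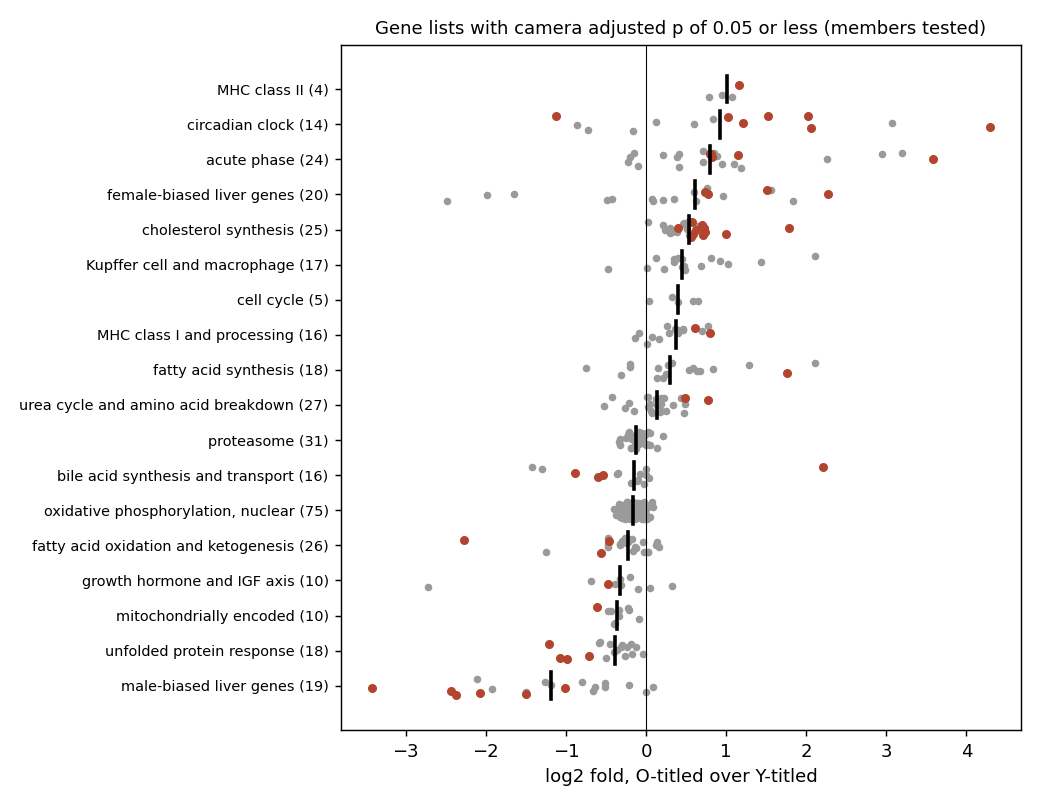
Log2 fold changes, O-titled over Y-titled, of the tested members of each list with a camera adjusted p of 0.05 or less; red points passed the edgeR test, grey points did not, and the black bar is the median. Medians run from -1.19 for male-biased genes to 1.01 for class II genes, and the number of tested members is in brackets.

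Of the DNA methylation and hydroxymethylation genes, the subject of the series title, none was called. In edgeR 0 of 8 tested members passed, over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. The list median was -0.08 (camera adjusted p = 0.886). Idh1 was at 481 ± 35.4 against 436 ± 38.0 CPM, Idh2 at 92.8 ± 29.0 against 73.2 ± 26.1, the methyl-CpG binding gene Mbd2 at 35.5 ± 7.23 against 45.7 ± 7.46 and the base excision gene Tdg at 8.27 ± 1.81 against 11.8 ± 2.28 CPM. The enzymes that write and oxidise methylcytosine lay under the count filter. Tet1 had 0 reads in every library, which allows up to between 1.16 and 5.50 CPM per library. Summed over O-titled and Y-titled libraries Tet2 had 7 and 9 reads, Tet3 23 and 17, Dnmt1 41 and 23 and Dnmt3a 31 and 25. The exact permutation p values of the last 4 genes were 0.143, 0.857, 0.914 and 0.771. Of the listed genes under the filter the demethylation-linked Gadd45a, named after its values were seen, had the smallest exact p, with 74 and 21 reads (exact p = 0.0857, adjusted p = 0.407).

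Females and males differed in the genes known for sex-biased expression in mouse liver. The sulfotransferases Sult2a1 and Sult2a2 stood at 618 ± 526 and 849 ± 477 CPM in females and at 0.0961 ± 0.192 and 0.528 ± 0.653 CPM in males. Mup20, the male urinary pheromone, was at 10242 ± 2399 CPM in males and 259 ± 121 CPM in females (log2 fold of females over males -5.39, SE 0.294, adjusted p = 3.49e-05). Elovl3 stood at 178 ± 136 CPM in males and at a mean of 4.92 CPM in females (log2 fold -5.21, SE 0.272, adjusted p = 2.82e-09).

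Of 6759 genes, 200 passed, 122 higher in females and 78 higher in males. The count was 125 without O-titled replicate 2, 127 without Y-titled replicate 1 and 65 without the title group as covariate. Other large female excesses, given as levels because males had at most a few reads, were in A1bg (804 ± 655 against 0.192 ± 0.384 CPM), Sult2a5 (66.9 ± 56.7 against 0.0961 ± 0.192 CPM), Xist (32.1 ± 3.56 against 0.288 ± 0.577 CPM), the cytochrome P450 gene Cyp2b13 (114 ± 43.6 against 0.673 ± 1.35 CPM) and the hydroxyacid oxidase Hao2 (21.6 ± 8.50 against 0.432 ± 0.634 CPM). Female over male log2 folds were 6.29 for Cyp2c69 and 6.28 for Cyp2a4. The most abundant female-biased genes were Ces1c (0.59), Adh1 (0.52), Mat1a (0.48), Fgl1 (0.44) and the chaperone Hspa8 (0.58), with smaller differences. On the male side, the fatty acid hydroxylase Cyp4a12a stood at 151 ± 105 CPM against 0.224 ± 0.449 CPM. The Y-linked Eif2s3y and Ddx3y stood at 42.8 ± 7.77 and 30.3 ± 5.66 CPM against 0 reads. Log2 folds were -5.33 for Hsd3b5, -5.29 for Mup21, -5.18 for Cyp2d9, -3.32 for complement C6 and -2.98 for Cyp2u1. Among abundant genes they were -0.57 for Serpina1c, -0.76 for the sterol carrier Scp2, -0.83 for Car3 and -0.53 for Phyh. A1bg (adjusted p = 0.12) and Cyp2b13 (0.0508) lost their calls without O-titled replicate 1, the male library with the few reads of these genes. Several fits without 1 library also ended the calls of Cyp2a4 (adjusted p up to 0.183), Cyp2c69 (0.143), Fgl1 (0.224), Mat1a (0.147), Hspa8 (0.116), Adh1 (0.0808), Phyh (0.0798), Cyp2d9 (0.0747) and Ces1c (0.0703).

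Of 19 tested male-biased list genes 13 were lower in females, 0 higher and 6 did not pass, and all 19 were lower adjusted over the list alone (median -2.40, camera adjusted p = 2.41e-48, still 0.0101 with an estimated correlation). They included Cyp7b1, an oxysterol hydroxylase (126 ± 18.8 against 23.9 ± 8.45 CPM), Gstp2 (128 ± 39.8 against 29.6 ± 6.26) and Ugt2b1 (401 ± 189 against 151 ± 46.4). Of 20 tested female-biased list genes 16 were higher in females, 0 lower and 4 did not pass, and all 20 were higher adjusted over the list alone (median 4.74, camera adjusted p = 9.41e-41, adjusted p = 0.0644 with an estimated correlation). Of 26 xenobiotic metabolism genes 6 were higher and 1 lower in females, with 8 and 1 adjusted over the list alone. Among them were Fmo1 (221 ± 41.9 against 88.2 ± 13.6 CPM), the sulfotransferase Sult1a1 (468 ± 46.6 against 239 ± 28.7), the bilirubin glucuronosyltransferase Ugt1a1 (341 ± 23.7 against 194 ± 20.8) and Por, the electron donor of microsomal P450 enzymes (372 ± 229 against 176 ± 68.8). The camera adjusted p was 5.24e-04, with adjusted p = 0.296 with an estimated correlation.

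Several interferon response genes were higher in females. Of 25 tested members 5 passed, all higher, 20 did not pass, and 17 passed adjusted over the list alone. They included the guanylate-binding protein Gbp3 (18.8 ± 6.11 against 5.98 ± 1.70 CPM), the chemokine Cxcl9 (28.0 ± 5.94 against 12.5 ± 3.76), Ifi27l2a (51.9 ± 16.7 against 27.2 ± 5.35) and Irgm2 (30.0 ± 3.78 against 16.5 ± 4.11). The median was 0.71 and the camera adjusted p 2.55e-13, with adjusted p = 0.296 with an estimated correlation. Cxcl9, Ifi27l2a and Irgm2 lost their calls without each of 2, 3 and 4 libraries, at adjusted p up to 0.0798, 0.127 and 0.119. Single members of other lists passed too, namely the cell cycle gene Ccnd1 (77.1 ± 17.3 in females against 27.7 ± 8.80 CPM in males), the haem synthesis gene Alas2 of red cells (15.8 ± 5.44 against 102 ± 20.6 CPM) and the stellate cell gene Lum (15.6 ± 3.54 against 7.06 ± 1.58 CPM), which lost its call without each single library (adjusted p up to 0.249). Also past the threshold were Psmb8 (71.0 ± 22.5 against 41.0 ± 7.42 CPM; not called without each of 6 libraries, adjusted p up to 0.189), Serpina3m, which overlaps other Serpina3 genes (531 ± 68.6 against 300 ± 102 CPM), Srebf1 (156 ± 104 against 231 ± 140 CPM) and the isocitrate dehydrogenase Idh2 (104 ± 20 against 61.7 ± 12.8 CPM; not called without each of 2 libraries, adjusted p up to 0.0736). Of the 271 and 200 genes that differed by title and by sex, 43 were shared, 32 in the same direction, against 8.02 for independent sets; both comparisons use the same 8 libraries.

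Within the sexes, 370 genes differed between O-titled and Y-titled females and 85 between O-titled and Y-titled males, and 26 differed in the size or direction of that difference. Depth was less even among the males, from 545171 to 2593200 mapped reads, against 1094237 to 1369069 in the females. The counts within the sexes therefore do not by themselves show a larger difference in females. Slco1a1, an organic anion transporter of the hepatocyte membrane, had 141 and 93.4 CPM in Y-titled females, 1.74 and 1.40 CPM, both under the floor of 3 reads, in O-titled females, and 378, 350, 213 and 242 CPM in Y-titled and O-titled males (adjusted p of the difference between the sexes 3.11e-07). G6pc, the last enzyme of glucose release, fell in females from 252 and 201 to 33.9 and 60.2 CPM and had a log2 fold of -0.03 in males (adjusted p of the difference 0.00421). Cyp2b9, a female-biased P450 gene, stood at 19.6 and 8.06 CPM in O-titled males against 0.629 and 0 in Y-titled males, and at 166, 206, 248 and 263 CPM in O-titled and Y-titled females (adjusted p = 0.00156).

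**Figure D3:**
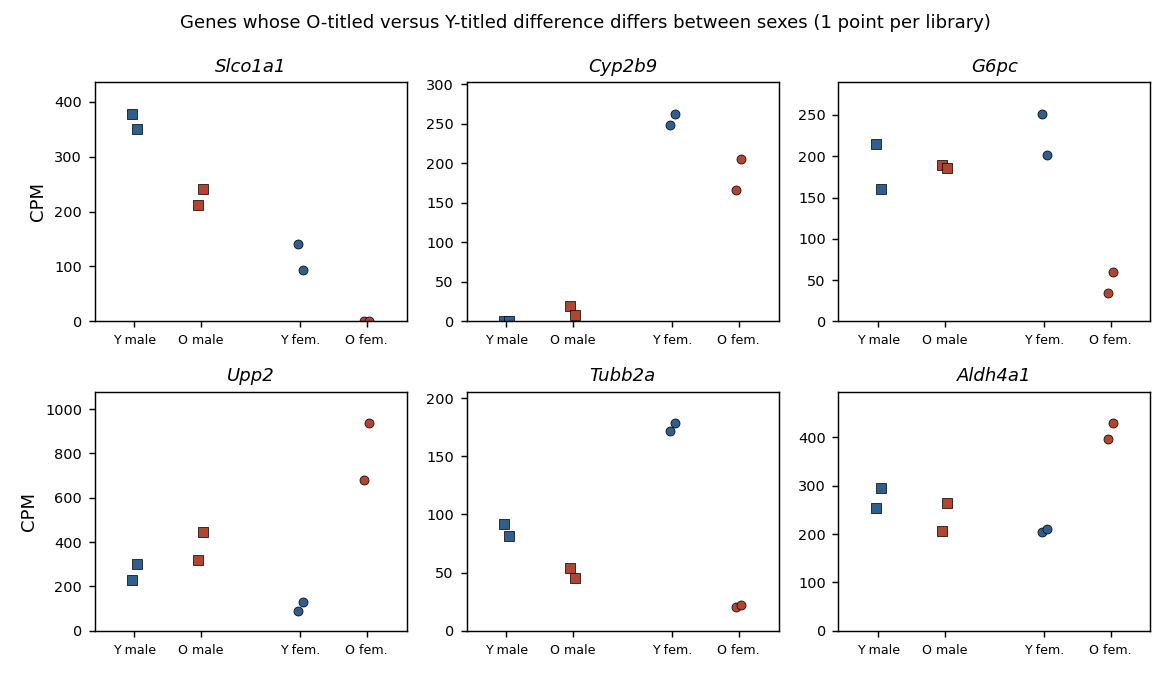
Expression of 6 genes per library, in CPM, in Y-titled males, O-titled males, Y-titled females and O-titled females, with 1 point per library. Slco1a1 lies under the floor of 3 reads in both O-titled females and above it in every other library.

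Further genes whose difference differed between the sexes were the tubulin genes Tubb2a (log2 fold -3.01 in females, -0.79 in males; adjusted p of the difference 5.01e-04) and Tubb4b (-1.56 and -0.12; 0.0168) and the elongase Elovl5 (-1.41 and -0.09; 0.0141). The others were the uridine phosphorylase Upp2 (2.89 and 0.53; 0.0175), the proline degradation enzyme Aldh4a1 (0.99 and -0.22; 0.0175), the interferon-induced Apol9a (1.64 and -0.46; 0.00609) and mt-Nd3 (-1.0 and 0.06; 0.0175). Of 24 acute phase genes 11 rose in females and 4 in males, and 4 had a higher female than male log2 fold, with 8 adjusted over the list alone (median of the difference 0.84, camera adjusted p = 1.08e-10, adjusted p = 0.524 with an estimated correlation). The 50 genes called in both sexes all moved in the same direction, where 4.65 shared genes would be met between independent sets. The sexes share no library, but both calls came from the same fit, with the spread shared over all 8 libraries. The sets are therefore not independent, and 4.65 is only a rough guide. With 2 libraries per sex and group the counts moved with single libraries, from 85 to 31 without O-titled replicate 1, 35 without Y-titled replicate 2 and 54 without Y-titled replicate 1 in males. In females it moved from 370 to 133 without Y-titled replicate 3 and 198 without Y-titled replicate 4. The 26 genes became 8 without O-titled replicate 1 or Y-titled replicate 2, 13 and 15 without Y-titled replicates 3 and 4, 16 without O-titled replicate 2 and 45 without O-titled replicate 4.

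Transcript usage within genes did not differ detectably between O-titled and Y-titled livers. Of 1236 genes with 2927 tested transcripts, diffSpliceDGE called 0 by the Simes method, with 10 at an unadjusted p under 0.05. It called 0 by its gene-level F test, with 46 at an unadjusted p under 0.05, where 61.8 would be met by chance. The Simes count of 10 lies far under that number, so the Simes test was conservative here and could have missed changes. A limma test of log2 odds called 0, with 63 at an unadjusted p under 0.05 and a smallest adjusted p of 0.170. Among the genes with the smallest Simes p were Pnkd, Acp5, Noct, Cfhr2, AW112010, Rps9, Igfbp2 and Cept1. In Noct, a clock-controlled gene, the transcript Noct-201 made up 33.0 ± 3.63% of the reads in O-titled and 14.3 ± 10.1% in Y-titled livers. In Pnkd the transcript Pnkd-202 made up 18.0 ± 7.04% against 41.3 ± 2.47%. Both genes had a Simes adjusted p that rounds to 1, and an adjusted p of 0.170 in the log2 odds test.

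Library composition did not separate the groups at an adjusted p of 0.05 in exact permutation tests of 11 measures, 6 of which were added after the data had been seen. The smallest adjusted p was 0.314, and 1 measure had an unadjusted p under 0.05. With 11 measures, 1 alone cannot reach an adjusted p of 0.05 in this design. The measure with the smallest p was the share of reads on transcripts of 3 kb or longer, 16.3 ± 0.858% in O-titled and 14.9 ± 0.382% in Y-titled libraries (exact p = 0.0286, the smallest this design allows). For each of 2500 transcripts with at least 20 reads in every library, the median read length was divided by the annotated transcript length. The median of this ratio over transcripts was 71.6 ± 3.22% in O-titled and 75.3 ± 1.52% in Y-titled libraries (exact p = 0.0571). Its lowest value, 67.1%, was in O-titled replicate 3.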

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

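The thresholds for values standing apart were fixed beforehand, while the tests of time of day, depth, shared reads and a single library were chosen only after the results were seen. For the age-linked genes, the share of splits was added to the decision after the first outcome. The same holds for the share of splits in the test of male-biased genes without near-identical copies, and for the number of called members in the tests of depth and of O-titled replicate 3.

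In 18 of 230 groups of 4 libraries, 1 library lay far from the other 3, where 11.5 would be met by chance at 1 in 20. In 6 of the 18 a few reads stood against 0 in the other libraries, which meets the rule by construction, so no excess over chance is shown. Among the genes that differed by title, Wee1 was at 3.59 CPM in Y-titled replicate 4 (1.84 to 1.98 in the other Y-titled libraries), Per2 at 5.04 in Y-titled replicate 1 (1.80 to 1.98), and Cyp7a1 at 198 in O-titled replicate 4 (80.7 to 95.4 in the other O-titled libraries). The Y-titled values of Wee1 and Per2 are a few reads each, partly under the floor of 3 reads, where counting error is large. Y-titled replicate 2, the library with the fewest reads, stood apart with Cdh1 at 57.4 CPM (25.7 to 28.3), Fdft1 at 79.2 (131 to 138) and Idh1 at 493 (414 to 421). The antigen presentation gene Cd74 was at 45.7 CPM in O-titled replicate 2 against 172 to 191 in the other O-titled libraries.

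Among the males, O-titled replicate 1, the deepest library, was the only male library with reads of Sult2a1 (0.384 CPM), A1bg (0.769), Sult2a5 (0.384), Cyp2b13 (2.69) and Xist (1.153). It also had the lowest Cyp2u1, at 19.6 CPM (30.2 to 31.7 in the other males), and the lowest Fmo1, at 68.0 CPM (93.0 to 97.6). Ugt1a1 was at 162 CPM in the male Y-titled replicate 2 (203 to 205). Among the females, Hspa8 was at 1341 CPM in Y-titled replicate 3 (980 to 1024), Lum at 20.8 in O-titled replicate 3 (13.3 to 14.4), and Cyp4a12a at 0.898 in Y-titled replicate 4 with 0 in the others.

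A difference between the sexes in the O-titled versus Y-titled comparison singled out 26 genes, and the 10 with the smallest p are given as female minus male log2 fold. Lower in females were Slco1a1 (-5.46, with both O-titled females under the floor of 3 reads), Cyp2b9 (-5.29, resting on 1 read in the Y-titled males), Tubb2a (-2.22), G6pc (-2.22), Tubb4b (-1.43), Elovl5 (-1.32) and mt-Nd3 (-1.06). Higher in females were Upp2 (2.35), Apol9a (2.10) and Aldh4a1 (1.22).

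The real grouping was set against all 34 ways of splitting the 8 libraries into 4 and 4 that can be told apart from the covariate. Counts of splits include the real one. For genes by title, only 1 of 34 splits, the real one, gave as many as 271, and the highest other gave 10. For genes by sex only 1 of 34 gave as many as 200, with 6 as the highest other. In the other splits real differences lie within the groups, where they widen the spread and lower the counts. The real split gave the most genes in both comparisons, but 34 splits of this kind cannot exclude chance. For the number of gene lists called chance cannot be excluded, since 2 of 34 splits gave at least the real 19 by title (highest other 21) and 4 of 34 at least the real 18 by sex (highest other 22). For single lists, not adjusted over the 39 tested, the real split alone had the largest absolute median in 6 by title and 4 by sex. By title these were the cholesterol (0.54, highest other 0.483), acute phase (0.80, 0.674), clock (0.93, 0.820) and male-biased lists (-1.19, 0.981). Nuclear oxidative phosphorylation (-0.159, 0.158) and the proteasome (-0.122, 0.121) completed them, each by a very narrow margin. By sex they included the male-biased (-2.40, 1.89) and female-biased lists (4.74, 3.08). By title the other lists that camera called did not stand out in this way, with a median as large in 2 of 34 splits for class I, 3 for the unfolded protein response and for the growth hormone axis, 4 for fatty acid oxidation, and 5 for mitochondrially encoded and class II genes. The number was 6 for female-biased and cell cycle genes, 7 for Kupffer cells, 9 for bile acids, 13 for fatty acid synthesis and 19 for the urea cycle. For transcript usage the real count was 0, which all 34 splits reach by construction, so the splits cannot inform about chance there.

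The titles and the age field name opposite ages: if the age fields were exchanged, genes known to rise with age would be higher in O-titled livers, and if the titles were exchanged they would be lower. The tested members were H2-Aa, H2-Ab1, H2-Eb1 and Cd74, the same 4 genes as the class II list, with a median log2 fold of 1.01 and a camera p of 4.87e-04, which meets the criterion for exchanged age fields as first written. However, 5 of 34 splits gave a median at least as large, the highest other being 1.32. Each of the others kept O-titled replicates 1, 3 and 4 and exchanged O-titled replicate 2 for a Y-titled library. The count therefore cannot tell chance from a low value in O-titled replicate 2, where Cd74 was at 45.7 CPM. The 3 tested genes known to fall with age had a median of -0.35 that camera did not call (adjusted p = 0.199). In males their median was -0.34 and the camera adjusted p 0.0497, with adjusted p = 0.426 with an estimated correlation. Of the listed members under the count filter, Jchain (87 reads in O-titled and 3 in Y-titled libraries) and Mzb1 (16 and 1) lay apart, each at exact p = 0.0286 and adjusted p = 0.211, the lowest that so few separated genes can reach, while Cd79a (30 and 10) and Cd79b (21 and 14) overlapped (exact p = 0.143 and 0.914). The class II genes, Jchain and Mzb1 lean towards exchanged age fields, but they also follow the number of immune cells in a sample and chance cannot be excluded for the median, so exchanged age fields and exchanged titles both stayed open.

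The clock genes differed by title. If the groups had been killed at different times of day, genes that peak late in the day would move against genes that peak early. The late minus early difference in log2 CPM was 2.60 ± 0.491 in O-titled and -0.888 ± 0.881 in Y-titled libraries, a gap of 3.49 without overlap (exact p = 0.0286). Clock genes had already been seen to separate the groups when this score was chosen, so its p adds no independent evidence. A shift of the clock with age could give the same pattern, and no time of sampling is in the labels, so a different hour and a biological change both stayed open. A different hour would bear on every gene compared by title. How far it reached the sterol, bile acid, unfolded protein response and other lists was not tested. Unequal depth was argued against, because at equal depth the median of the clock list was 0.91 with 4 members called.

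The male-biased genes were lower in O-titled livers. If reads shared between near-identical genes were the cause, members without such copies would lie near 0. Their median was -0.66 and so not near 0, but 2 of 34 splits, the real one included, gave a median as large (highest other 0.661). A fall beyond chance was not shown for these members as a set, so the test could not decide and shared reads stayed open. O-titled replicate 3, the library with few Mup reads, was argued against as the sole cause, since without it the median was -1.08 and all 6 called members stayed called. A weaker growth hormone signal could lower the same genes, and no measurement of the hormone was available to test it.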

How the results depend on the processing

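No result past its threshold changed direction under any alternative; thinning, the log2 odds test and the list settings for age-linked genes were chosen only after the results were seen. The 271 genes by title became 600 with no low-count filter (more genes tested), 134 with no sex covariate, 144 at equal depth (fewer reads) and 154 (without Y-titled replicate 4) to 294 (without O-titled replicate 2); DESeq2 gave 238 and limma voom 251. The 200 by sex became 401 with no filter, 65 with no group covariate, 121 at equal depth and 125 (without O-titled replicate 2) to 217 (without O-titled replicate 3). The 26 for the difference between the sexes became 100 with no filter, 15 with limma voom and 8 (without O-titled replicate 1) to 45 (without O-titled replicate 4). Within males 85 became 211 with no filter, 55 with limma voom and 31 (without O-titled replicate 1) to 127 (without O-titled replicate 3). Within females 370 became 191 with DESeq2 and 133 (without Y-titled replicate 3) to 371 (without O-titled replicate 2). The 19 lists by title became 0 with an estimated correlation and 4 with fry, and the 18 by sex 1 and 2. The age-linked genes, whose median of 1.01 does not depend on the list test, had adjusted p = 0.368 with an estimated correlation and 0.154 with fry. Beyond those given with their construction, the cause was not tested.

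Of 53 called genes named for the comparison by title, 23 kept their call in every setting that tested them. In the fits without 1 library that tested them, 32 kept it. Of 47 by sex, these numbers were 21 and 30. Slc5a6, Wee1, Nrg4 and Per2, for example, were tested in only 16 of 18 settings by title. Transcript usage stayed at 0 throughout, while the composition tests were too small for single measures to pass. With the replicate number as a block 184 genes differed by title. Deviations from sex and group means correlated at -0.0649 and -0.0275 between libraries of the same number. With 2 libraries per sex and group these deviations mirror each other, so the correlations cannot show whether same-numbered libraries share more than a number. Depth limits detection to 3 reads, between 1.16 and 5.50 CPM.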

Other observations

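Further clock genes, a plasma cell gene and matrix genes were chosen after their values were seen. Of these Dbp did not pass, and Arntl and Jchain lay under the count filter. Dbp, a clock output factor, stood at 139 ± 21.4 CPM in O-titled and 16.8 ± 16.8 CPM in Y-titled livers in edgeR (adjusted p = 0.0868). Arntl (Bmal1), the core activator of the clock, had 5 reads in O-titled and 49 in Y-titled libraries, at 0.680 ± 0.491 and 12.5 ± 4.19 CPM (exact p = 0.0286, adjusted p = 0.211). Jchain, which joins antibody chains in plasma cells, had 87 and 3 reads, at 14.3 ± 6.94 and 0.611 ± 0.428 CPM (exact p = 0.0286, adjusted p = 0.211). For both genes the exact p is the smallest this test allows, and the adjusted p is the lowest that so few separated genes can reach. The O-titled over Y-titled ratio was 0.0740 for Arntl (95% binomial interval 0.0230 to 0.185) and 21.0 for Jchain (6.96 to 104). These intervals cover counting error only. Of 13 tested stellate cell and fibroblast genes 2 rose, the matrix proteoglycans Dcn and Bgn, with log2 folds of 0.58 and 0.71, and 4 rose adjusted over the list alone (camera adjusted p = 0.0985).

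In females, where Y-titled replicate 4 had 11.1% of its reads on mitochondrially encoded genes against 6.82 to 8.66% in the other females, 6 of 10 mitochondrially encoded genes fell, with 8 adjusted over the list alone (camera adjusted p = 7.95e-10, adjusted p = 0.314 with an estimated correlation), while in males their median log2 fold was -0.07 and camera did not call them (adjusted p = 0.55). The female minus male difference of these genes had a median of -0.64 (camera adjusted p = 1.72e-08, adjusted p = 0.524 with an estimated correlation). Of 18 fatty acid synthesis genes 3 rose in males, with 9 adjusted over the list alone, and in females 1 rose and 1 fell, also adjusted over the list alone. The camera adjusted p of the difference between the sexes was 5.81e-08, with adjusted p = 0.524 with an estimated correlation.

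Between females and males, camera also called the lists of liver endothelial cells, MHC class II, the proteasome, Kupffer cells and the unfolded protein response, at adjusted p = 0.00427, 0.0018, 0.0133, 0.0309 and 0.0457. With an estimated correlation these were adjusted p = 0.367, 0.367, 0.531, 0.712 and 0.712. In edgeR 0 of their 18, 4, 31, 17 and 18 members passed, 5, 2, 2, 2 and 4 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0. Only Kupffer cell genes had any higher in females adjusted over the list alone, namely 2.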
